A study of Mus musculus with 44 samples.

How the data were processed

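RNA from the left ventricle of 44 mice was measured on Affymetrix 430A 2.0 arrays, with 1 array per mouse. The mice carried a PKCε transgene, a model of dilated cardiomyopathy, or were nontransgenic FVB/N controls (called FVB here). Each line was given control IgG (10 mice) or FG-3149 (12 mice), an antibody against connective tissue growth factor (CTGF), the product of Ccn2. The dose was 30 mg/kg with 2 injections per week for 3 months from the age of 3 months, tissue was taken at 6 months, and 250 ng of RNA entered each preparation. By the labels, 7 of the 10 FVB IgG mice, 6 of the 12 FVB antibody mice, 5 of the 10 PKCε IgG mice and 6 of the 12 PKCε antibody mice were female.

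The deposited values are ratios on a linear scale. The authors processed the array files by GCRMA (version not given) and divided each probe set by its median over the arrays in GeneSpring GX 7.3.1. On checking, all 22690 probe sets had a median within 0.001 of 1. The ratios ran from 0.01 to 1104, and 25 of them stood at the lowest value. The brightness of each probe set and any detection call are no longer in the values, so signal over background is unknown and the number of arrays limits the precision. Array medians ran from 0.954 to 1.032. No genome build is named, so no coordinates are given.

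Log2 of each ratio was taken. Of the probe sets, 20393 matched 1 gene, 691 matched several and 1606 had no gene name, with 64 controls counted among these. For 4958 genes with more than 1 probe set, the probe set with the largest SD over all arrays was used, chosen without regard to group, which left 12394 genes. Groups were compared in 1 limma fit (limma 3.58.1 in R 4.3.3, lmFit and eBayes) with a term for sex, and p values were adjusted by the Benjamini-Hochberg method over all genes of each comparison. A gene was called changed at an adjusted p under 0.05. Changes are log2 differences with the SE of the fit, all tests are two-sided, and a positive value means higher in the group named first. Sex interactions used the means of 8 cells of group and sex.

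Before the data were examined, 45 gene lists were fixed (pathways, complexes and markers of the cell types a heart sample could hold), together with the tests, the alternatives and the rule for naming genes. Lists were tested with limma camera at a preset inter-gene correlation of 0.01, and again with the correlation estimated for each list. Which lists are described was chosen after their results were seen. The rule named Ccn2, Prkce, Myh6 and Nppa always, the 10 called genes with the largest change in each direction, and up to 4 members with the lowest p of each list described. For sex it named the sex-linked genes and the 5 genes with the lowest adjusted p.

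The return of PKCε-changed genes under the antibody was measured as a covariance across genes of the PKCε effect with the antibody effect. The PKCε IgG arrays were divided at random within sex 100 times, so that the effects shared no PKCε IgG array, and the value for simulated unchanged groups stands beside it. Each count of genes or lists was compared with 100 splits of the same arrays into groups of the same sizes.

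Array scores were made after the data were seen. The atrial marker level is the mean log2 ratio of Sln, Myl7 and Myl4, and 10 arrays above 4 were left out in an alternative. The clock score is the mean of Per1, Per2, Per3, Dbp, Tef, Hlf, Nr1d1 and Nr1d2 minus that of Arntl, Clock and Npas2. The Gapdh 3' minus 5' difference of control probe sets served as a sign of RNA quality, with that of Actb beside it. Scores were compared by permutation tests (100000 resamples) without a term for sex, and adjusted over all scores and comparisons.

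Alternatives were no sex term, a replicate block, a residual principal component, 2 array scalings, a filter on low SD, a floor, a pseudocount of 0.1, all or averaged probe sets, robust eBayes, array weights, fewer groups or mice, a threshold of 0.01, a fold of 1.5, and leaving out each array. Added after the data were seen were the atrial marker level, clock score and Gapdh difference as covariates, the runs without the 10 arrays or without 2 arrays whose Sftpc and Scgb1a1, markers of lung, both lay above 3, and leaving out each array for the lists. The test was tried on simulated data with independent normal noise for each gene, in which 0 genes were called in the wrong direction. For the antibody in PKCε mice, it called 41.8%, 89.6% and 100% of simulated changes of 0.25, 0.5 and 1 on the log2 scale. Correlated genes and admixed tissue were not simulated, so these rates may not hold for the real arrays. Protein levels, heart function and survival were not analysed here.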

Results

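Left ventricular RNA was profiled in 44 mice on 1 array each, in 4 groups: FVB mice (10 given IgG, 12 given FG-3149) and PKCε transgenic mice (10 given IgG, 12 given FG-3149). FG-3149 blocks CTGF, a matricellular protein that promotes fibrosis. Values are log2 ratios of each gene to its median over the 44 arrays, and 12394 genes were tested. The first principal component held 33% of the variance, with means of 35.0 ± 6.42 (SD, n = 5) in PKCε IgG females, 10.0 ± 3.62 (n = 5) in PKCε IgG males and -21.8 ± 3.08 (n = 6) in FVB antibody females. PKCε antibody males (3.85 ± 6.38, n = 6) and FVB IgG females (-4.72 ± 14.8, n = 7) met within their spread. Xist, the RNA that silences an X chromosome in females, was higher on every female array (lowest -0.71) than on any male array (highest -2.69), and 14 of the 20 male arrays stood at the lowest deposited value. The Y-linked genes Uty and Kdm5d were lower by -4.50 ± 0.19 (SE) and -3.99 ± 0.15. FVB FG-3149 replicate 11, labelled female, had a Uty value of 3.63, against at most 0.023 on the other female arrays.

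The comparison of PKCε IgG with FVB IgG mice asks how the lines differed under the control antibody. Myh7, the slow beta myosin heavy chain of the fetal ventricle, rose by 3.22 ± 0.13 on the log2 scale, or 9.34-fold (adjusted p = 5.05e-22). All 10 transgenic arrays lay above every FVB IgG array for this gene. Skeletal actin Acta1 rose 4.90-fold (2.29 ± 0.22), and the adult alpha myosin heavy chain Myh6 fell by 1.49 ± 0.14. Another probe set of Myh6 gave -0.17. Fibrillar matrix genes rose in 29 of 34 cases and fell in 1, though the list was not called with an estimated correlation (adjusted p = 0.0956). Ltbp2, which binds fibrillin microfibrils, rose by 2.79 ± 0.29, the collagen Col8a1 by 2.32 ± 0.16, and periostin (Postn), a matricellular protein of activated fibroblasts, by 2.29 ± 0.24. Genes of fatty acid oxidation fell in 26 of 31 cases, a list not called with an estimated correlation either (adjusted p = 0.161). Acaa2, the last thiolase step of mitochondrial beta oxidation, fell by 1.72 ± 0.18. All 10 transgenic arrays lay below every FVB IgG array for Acaa2.

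In all, 5235 of the 12394 genes changed, 2566 higher and 2669 lower. Of these, 290 differed at least 2-fold (183 higher, 107 lower). The 10 largest rises also held Lman1l (2.67 ± 0.16), the growth factor Fgf6 (2.60 ± 0.24), the cysteine protease inhibitor Cst6 (2.27 ± 0.20), the homeobox gene Meox1 (2.24 ± 0.18) and Dio2 (2.30 ± 0.28), the deiodinase that makes active thyroid hormone. The largest falls were in Cyp2b10, a cytochrome P450 (-4.21 ± 0.39, 18.5-fold), and the water channel Aqp4 (-3.05 ± 0.34, 8.31-fold), each below every FVB IgG array on all 10 transgenic arrays. Ces1d, a carboxylesterase, fell by 2.78 ± 0.19, the protease Tmprss13 by 2.77 ± 0.22 and the phospholipase Pla2g5 by 2.31 ± 0.23. Hamp, the iron hormone hepcidin, fell by 2.57 ± 0.80, and Cyp2e1 by 2.35 ± 0.43. For both, the FVB IgG mean alone stood high (3.04 ± 3.22 and 2.19 ± 1.62, SD), against at most 0.57 and 0.039 in the other groups. Ccn2, the gene of the antibody's target, rose by 0.74 ± 0.23 (adjusted p = 0.00756), above the FVB IgG median on 9 of 10 arrays. Prkce rose by 0.49 ± 0.15 at 1 probe set, while another fell by 0.57. Their mean was -0.041 (adjusted p = 0.752), so the level of Prkce was not settled.

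Of the 10 measured genes of the fetal cardiac programme, 9 rose and 1 fell, the same counts when adjusted over the list alone. The fall was in Tnni1 (-0.47 ± 0.13), named after its value was seen. It was the only list of this comparison called with an estimated correlation (adjusted p = 0.036). Enah, an actin regulator, rose by 1.30 ± 0.11, Fhl1, a LIM protein of stressed muscle, by 1.06 ± 0.086, and Nppa, the atrial natriuretic peptide, by 1.97 ± 0.46. Nppa varied widely in FVB IgG mice (SD 1.92). It ran from -3.71 on replicate 7 to 0.89 on replicate 2, where atrial marker levels were 0.49 and 8.47. All 10 PKCε IgG arrays lay above the FVB IgG median for Nppa, but 0 above every FVB IgG array. Of 34 fibrillar matrix genes, 29 rose and 1 fell, with the same counts adjusted over the list alone (adjusted p = 0.0956 with an estimated correlation). Thbs4 (2.19 ± 0.16), Col5a1 (1.20 ± 0.095) and Col6a3 (1.15 ± 0.093) were among them. Of 15 basement membrane genes, 11 rose and 0 fell, as when adjusted over the list alone (adjusted p = 0.0956 with an estimated correlation). Among them were Col4a2 (0.91 ± 0.11) and the laminin Lama2 (0.69 ± 0.060). TGF-beta signalling had 17 of 25 members higher, also adjusted over the list alone (adjusted p = 0.134 with an estimated correlation). Tgfb2 rose by 1.77 ± 0.15 and the receptor Tgfbr2 by 0.79 ± 0.097, but other probe sets of Tgfbr2 gave -0.12 and 0.028. Of 15 integrins 8 rose and 1 fell, as when adjusted over the list alone (adjusted p = 0.0983 with an estimated correlation). They were led by Itgb5 (1.27 ± 0.092) and Itga9 (1.28 ± 0.12, with 0.96 and -0.25 at other probe sets). Fibroblast markers rose alongside these matrix groups, 11 of 15 and 13 adjusted over the list alone (adjusted p = 0.177 with an estimated correlation). Mfap5 rose by 1.99 ± 0.18 and Pi16 by 1.38 ± 0.13. Cell cycle genes rose in 10 of 27 cases, also adjusted over the list alone (adjusted p = 0.597 with an estimated correlation). Ccnd1 stood at 1.02 ± 0.13 and Mcm6 at 0.78 ± 0.17.

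In 3 lists of mitochondrial metabolism most members fell, though none of these was called with an estimated correlation. Glycolysis and glucose uptake, not called as a list, had 6 of 21 members lower and 2 higher. All 20 measured genes of the TCA cycle fell, also adjusted over the list alone (adjusted p = 0.0956 with an estimated correlation). Suclg1 stood at -0.63 ± 0.053 and Sdhb at -0.41 ± 0.038. Of 31 genes of fatty acid oxidation, 26 fell and 0 rose, the same adjusted over the list alone (adjusted p = 0.161 with an estimated correlation). Cpt2, which readies imported fatty acids for oxidation inside mitochondria, fell by 0.84 ± 0.090 and Etfa by 0.58 ± 0.058. Of 66 genes of oxidative phosphorylation, 48 fell, 51 adjusted over the list alone (adjusted p = 0.16 with an estimated correlation). Each fell by little, such as Uqcrfs1 (-0.49 ± 0.041) and Cox5b (-0.41 ± 0.043). Markers of ventricular cardiomyocytes moved with these lists: 7 of 13 were lower, and 7 lower with 1 higher adjusted over the list alone (adjusted p = 0.444 with an estimated correlation). Their mean was 0.074 ± 0.13 (SD) in FVB IgG and -0.20 ± 0.12 in PKCε IgG mice. Ion channels and calcium handling were not called as lists (adjusted p = 0.414 and 0.597 with an estimated correlation), though more members fell than rose. Of 23 ion channel genes 12 fell and 3 rose, and of 18 calcium handling genes 9 fell and 2 rose, also adjusted over the list alone. The connexin Gjc1 (1.15 ± 0.081) and the transcription factor Irx3 (1.03 ± 0.16) rose, and the potassium channel Kcnq1 (-0.74 ± 0.088) and phospholamban Pln (-0.41 ± 0.067) fell. Triadin (Trdn) rose by 0.998 ± 0.17 at the probe set used, while others gave -0.53, -0.49, -0.34, -0.27 and 0.26. The mean of its probe sets was -0.061 (adjusted p = 0.446), so the level of Trdn was not settled. Protein kinase C genes rose in 4 of 8 cases, also adjusted over the list alone (adjusted p = 0.282 with an estimated correlation), led by Prkca (0.80 ± 0.087) and Prkci (0.39 ± 0.060). Other probe sets gave 0.41 for Prkca and -0.13 for Prkci. In the CCN family, not called as a list, Ccn5 rose by 1.38 ± 0.26 and Ccn3 fell by 1.25 ± 0.24.

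Adipocyte markers were lower in PKCε IgG mice, 8 of 10 and 8 adjusted over the list alone (adjusted p = 0.542 with an estimated correlation). They held adiponectin Adipoq (-2.25 ± 0.49), Car3 (-2.22 ± 0.43) and Cidec (-1.25 ± 0.27), and with them Ucp1 of brown fat (-2.18 ± 0.56). Among atrial markers, not called as a list, Stard10 fell by 1.47 ± 0.44. The mean over the adipocyte markers was 1.13 ± 1.18 (SD, n = 10) in FVB IgG mice, against -0.15 in FVB antibody, -0.11 in PKCε IgG and -0.12 in PKCε antibody mice. The atrial marker level of PKCε IgG minus FVB IgG arrays was -2.96 (permutation p = 0.0801, adjusted p = 0.175), and of the 10 arrays where it was high 5 were FVB IgG and 2 PKCε IgG. Without those 10, adipocyte markers were lower in 4 of 10 cases and higher in 1. Adipoq (-1.72, adjusted p = 0.0152) and Car3 (-1.70, adjusted p = 0.00583) were still called, Ucp1 was -1.09 and Cidec -0.60, while Hamp (-0.56, adjusted p = 0.454) and Stard10 (-0.30, adjusted p = 0.0595) were not called. In males alone Adipoq (-1.67, adjusted p = 0.127), Car3 (-1.66, adjusted p = 0.0773) and Hamp (-0.11, adjusted p = 0.891) were not called either. The Gapdh 3' minus 5' difference, a sign of RNA quality, was 0.332 higher in PKCε IgG than in FVB IgG arrays (permutation p = 5e-05, adjusted p = 0.0012). It so moved with the matrix and the metabolic groups alike. The Actb difference, the other such sign, was -0.0115 there (permutation p = 0.897, adjusted p = 0.969) and did not move with them. With the Gapdh difference as a covariate 3881 genes changed. The test was limma on all arrays. Males alone gave 2169 genes, from 5 transgenic and 3 FVB mice. The groups also came from separate runs of mouse numbers, 192 to 362 in PKCε IgG and 420 to 443 in FVB IgG mice.

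Lung markers were high on PKCε IgG replicate 9, with Sftpc at 9.32, Sftpa1 at 6.87 and Scgb1a1 at 10.1. That array also had the highest Ltbp2 (4.43), Postn (3.32) and Timp1 (3.45) of its group. PKCε IgG replicate 10 had Sftpc at 3.53 and Scgb1a1 at 3.71, and replicate 7 had Sftpc at 1.64. FVB IgG replicate 4 had a Scgb1a1 value of 9.36, with Sftpc at 0.71. Scgb1a1 was also high on FVB IgG replicates 5 (4.59) and 9 (5.08) and FVB FG-3149 replicates 5 (3.10), 6 (5.17) and 7 (4.47). On PKCε FG-3149 replicate 7 it was 4.74. Sftpc was at most 0.91 on these further arrays. Without PKCε IgG replicates 9 and 10 the PKCε effect under IgG held 4256 genes, with 28 fibrillar matrix genes higher and 2 lower, and Ltbp2 at 2.50.

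**Figure D1:**
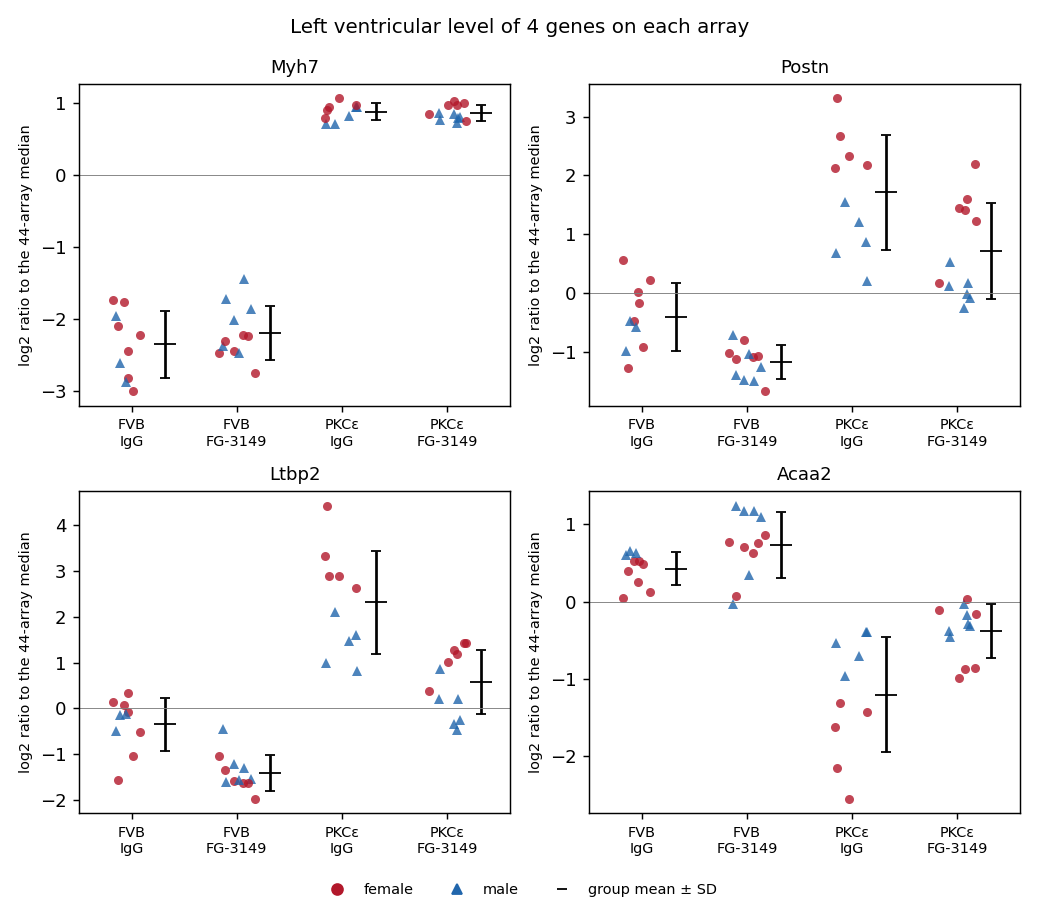
Log2 ratio of Myh7, Postn, Ltbp2 and Acaa2 to the median over the 44 arrays (vertical axis) in the 4 groups (horizontal axis); each point is 1 mouse, circles female and triangles male, with the group mean and SD as bars. Ltbp2 means were 2.32 in PKCε IgG and 0.58 in PKCε FG-3149 mice, while Myh7 means were 0.87 and 0.86.

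The antibody comparison in PKCε mice (12 given FG-3149 against 10 given IgG) asks what CTGF inhibition altered in the diseased ventricle. Ltbp2 fell by 1.74 ± 0.27 on the log2 scale, or 3.35-fold (adjusted p = 6.65e-05), below the PKCε IgG median on all 12 antibody arrays. Timp1, an inhibitor of matrix proteases, fell by 1.30 ± 0.26, Dio2 by 1.49 ± 0.26, the growth factor epiregulin (Ereg) by 1.46 ± 0.24 and the transferrin receptor Tfrc by 1.07 ± 0.16 (below every PKCε IgG array on 10 of 12). Other probe sets gave -1.01 and -1.18 for Dio2 and from -0.60 to 0.043 for Tfrc. Of 31 genes of fatty acid oxidation 15 rose, though 0 in males alone, 5 with the Gapdh difference as a covariate, and the list was not called with an estimated correlation. Among them Acaa2 rose by 0.82 ± 0.17, or 1.77-fold, above the PKCε IgG median on all 12. Of 16 clock genes 8 rose and 3 fell, though the list was not called with an estimated correlation (adjusted p = 0.41). Per2 rose 2.58-fold (1.37 ± 0.24), and Arntl, which encodes the activator BMAL1, fell by 1.43 ± 0.30. Another probe set of Per2 gave a smaller rise, 0.33.

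In this comparison 1093 genes changed, 630 higher and 463 lower, 15 of them at least 2-fold (4 higher, 11 lower). The 10 largest rises also held Lgi1 (1.15 ± 0.20), Rasd2 (1.05 ± 0.14), Ces1d (0.96 ± 0.18), the chemokine Cxcl1 (0.90 ± 0.25), Nampt, the rate-limiting enzyme of NAD salvage (0.89 ± 0.12), and Irgm2 (0.88 ± 0.29). The largest falls also held the matrix protein Spon2 (-1.23 ± 0.21), the cytokine Il6 (-1.09 ± 0.28) and Ecrg4 (-1.08 ± 0.34). Myh6 rose by 0.62 ± 0.13 (adjusted p = 0.00232), and was 0.048 (unadjusted p = 0.17) at another probe set. Myh7 had means of 0.87 ± 0.12 (SD, n = 10) under IgG and 0.86 ± 0.11 (n = 12) under the antibody. Ccn2 was -0.35 ± 0.21 (adjusted p = 0.363), Nppa -0.39 ± 0.43 (adjusted p = 0.665) and Prkce 0.14 ± 0.14 (adjusted p = 0.602), none of them called.

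Of 34 fibrillar matrix genes, 15 fell and 0 rose, and 21 fell adjusted over the list alone (adjusted p = 0.41 with an estimated correlation). Versican Vcan fell by 0.82 ± 0.18, Col5a2 by 0.78 ± 0.17, Col8a1 by 0.73 ± 0.15 and fibulin Fbln2 by 0.58 ± 0.12. Of 15 basement membrane genes 4 fell, as when adjusted over the list alone (adjusted p = 0.47 with an estimated correlation). Col4a1 stood at -0.60 ± 0.11 and Col4a2 at -0.50 ± 0.10. Matrix proteases and inhibitors fell in 4 of 22 cases and, adjusted over the list alone, in 6 with 1 higher (adjusted p = 0.47 with an estimated correlation). The aggrecanase Adamts4 fell by 0.84 ± 0.13 and tissue plasminogen activator Plat by 0.52 ± 0.094. TGF-beta signalling fell in 4 of 25 cases, 5 adjusted over the list alone (adjusted p = 0.527 with an estimated correlation), with Inhba at -0.39 ± 0.10. In the fetal programme 1 of 10 genes fell, also adjusted over the list alone (adjusted p = 0.458 with an estimated correlation). This was Fhl1 (-0.55 ± 0.082), while Enah was -0.26 ± 0.10 (adjusted p = 0.108). Of 27 cell cycle genes 1 fell, Mcm6 (-0.50 ± 0.16), and 12 adjusted over the list alone (adjusted p = 0.458 with an estimated correlation). Nusap1 stood at -0.54 ± 0.19 (adjusted p = 0.0629) and at 0.13 on another probe set. Fibroblast markers moved with the matrix lists, 3 of 15 lower, also adjusted over the list alone (adjusted p = 0.5955 with an estimated correlation), and 1 of 22 macrophage markers was lower, also adjusted over the list alone (adjusted p = 0.639 with an estimated correlation).

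Of 31 genes of fatty acid oxidation 15 rose and 0 fell, 20 adjusted over the list alone (adjusted p = 0.41 with an estimated correlation). Echs1 stood at 0.46 ± 0.079, Hadh at 0.42 ± 0.068 and lipoprotein lipase Lpl at 0.32 ± 0.066. TCA cycle genes rose in 11 of 20 cases, 16 adjusted over the list alone (adjusted p = 0.41 with an estimated correlation). Sdhc stood at 0.36 ± 0.071 and Idh2 at 0.28 ± 0.065. Of 66 genes of oxidative phosphorylation 12 rose, 19 adjusted over the list alone (adjusted p = 0.583 with an estimated correlation). Ndufs3 stood at 0.15 ± 0.042 and Atp5pb at 0.15 ± 0.040. Beside these lists 4 of 13 ventricular cardiomyocyte markers were higher, also adjusted over the list alone, though not called as a list. Calcium handling rose in 6 of 18 cases, also adjusted over the list alone (adjusted p = 0.4928 with an estimated correlation), with the channel subunit Cacnb2 at 0.58 ± 0.12 and S100a1 at 0.42 ± 0.092. MHC class II genes rose in 2 of 6 cases, 3 adjusted over the list alone (adjusted p = 0.573 with an estimated correlation), with H2-Ab1 at 0.71 ± 0.22 and Cd74 at 0.54 ± 0.17. Cytokines, not called as a list, held falls in Il6 and in Lif (-0.40 ± 0.11), and the CCN family held no call, with Ccn3 at 0.45 ± 0.23 (adjusted p = 0.243) and Ccn5 at -0.46 ± 0.25 (adjusted p = 0.283).

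Of 16 circadian clock genes, 8 rose and 3 fell, 10 and 3 adjusted over the list alone (adjusted p = 0.41 with an estimated correlation). Hlf (1.23 ± 0.21), Per3 (0.98 ± 0.21), Dbp (0.89 ± 0.28) and Nr1d2 (0.65 ± 0.10), which rise and fall with the repressor arm of the clock, rose, and Npas2, a partner of BMAL1, fell by 1.44 ± 0.29. Other probe sets gave -0.0016 for Npas2, 0.019 and 0.47 for Per3, 0.29 for Nr1d2, 1.15 for Hlf and 1.03 for Dbp. The clock score was 1.89 higher in PKCε antibody than in PKCε IgG arrays (permutation p = 0.00017, adjusted p = 0.00204), and 0.064 higher between the FVB groups (permutation p = 0.906, adjusted p = 0.969). This score was made after the data were seen and holds genes called in PKCε mice, so its p there is no separate support. The Gapdh 3' minus 5' difference was -0.26 lower under the antibody in PKCε mice (permutation p = 0.00076, adjusted p = 0.00608), beside the matrix, metabolic and clock groups alike. The Actb difference was -0.144 there (permutation p = 0.117, adjusted p = 0.187). With the clock score as a covariate 463 genes changed, with 4 fibrillar matrix genes lower and 12 of fatty acid oxidation higher. Timp1 (-0.92, adjusted p = 0.108) and Spon2 (-0.62, adjusted p = 0.131) were no longer called. With the Gapdh difference as a covariate 480 changed, with 9 and 5, and Acaa2 was 0.43 (adjusted p = 0.0976).

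**Figure D2:**
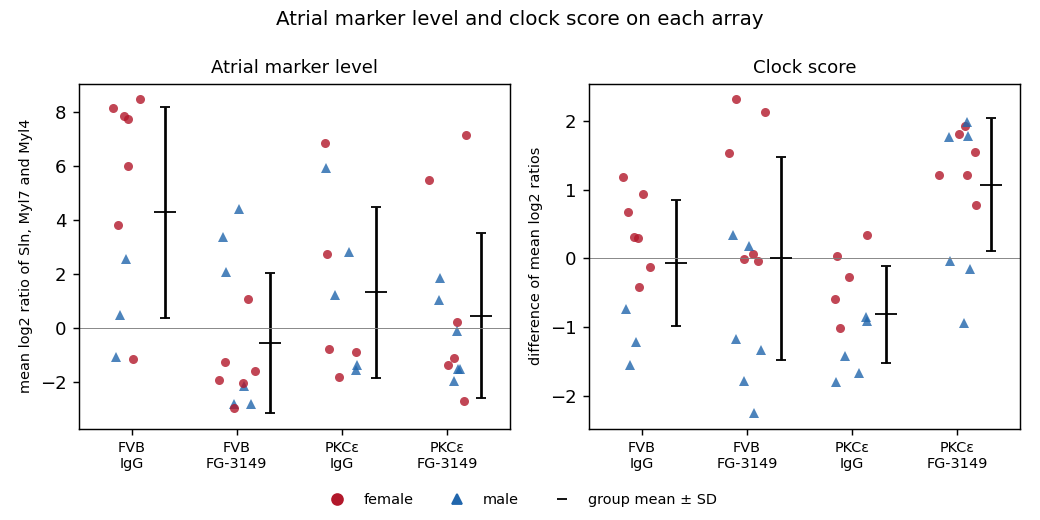
Atrial marker level, the mean log2 ratio of Sln, Myl7 and Myl4, and clock score, a difference of mean log2 ratios (vertical axes), in the 4 groups (horizontal axis); each point is 1 mouse, circles female and triangles male, with the group mean and SD as bars. Mean clock scores were -0.82 in PKCε IgG and 1.07 in PKCε FG-3149 mice, and mean atrial marker levels were 4.28 in FVB IgG and -0.55 in FVB FG-3149 mice.

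The mice of the PKCε groups also came from different runs of mouse numbers: all 5 IgG females were numbered 322 to 362 and all 5 IgG males lay in the run 190 to 196, while 9 of the 12 antibody mice were numbered 38 to 49. Among PKCε mice numbered 150 to 196 (3 females given antibody and 5 males given IgG, with the sex effect taken from the other groups), 347 genes changed, 88 of them shared. In these mice Ltbp2 (0.040), Dio2 (0.078), Fbln2 (0.086), Col8a1 (0.40), Vcan (0.039), Col5a2 (0.36), Col4a2 (0.13), Ecrg4 (0.41), Acaa2 (-0.071), Myh6 (-0.11) and Atp5pb (-0.0095) had the opposite sign without being called. Females alone gave 808 genes, with 10 fibrillar matrix genes lower and 16 of fatty acid oxidation higher, and males alone 57, with 3 and 0. Without PKCε IgG replicates 9 and 10, the arrays with high Sftpc and Scgb1a1, 440 genes changed, with 9 fibrillar matrix genes lower and 8 of fatty acid oxidation higher. Ltbp2 (-1.47, adjusted p = 0.000911), Timp1 (-1.18, adjusted p = 0.00681) and Acaa2 (0.58, adjusted p = 0.0195) were still called there. Cxcl1 (0.82), Irgm2 (1.001), Ecrg4 (-0.78), Dbp (0.91), Mcm6 (-0.52), Lif (-0.38), Ndufs3 (0.10) and Atp5pb (0.11) lost the call. Without the 10 arrays of high atrial marker level 528 genes changed, and with quantile normalization 726.

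The antibody comparison in FVB mice (12 given FG-3149 against 10 given IgG) asks what differed under the antibody without the transgene. The largest falls were in markers of atrial muscle: the atrial light chain Myl7 fell by 5.01 ± 1.40 on the log2 scale (32.2-fold, adjusted p = 0.0178), sarcolipin (Sln), which inhibits the calcium pump, by 4.92 ± 1.41, and Myl4 fell by 4.001 ± 1.17. Other probe sets gave less, -1.51 for Sln and -0.60 for Myl4. Dkk3 fell by 2.77 ± 0.51, and Nppa by 1.79 ± 0.44. Adipocyte markers fell in 6 of 10 cases, though the list was not called with an estimated correlation (adjusted p = 0.209). Car3 was lower by -2.36 ± 0.41, Adipoq by -2.25 ± 0.47 and Ucp1 by -2.13 ± 0.53. Among smaller rises were Sin3a, a corepressor scaffold (0.74 ± 0.098, adjusted p = 1.72e-06), and Rgs5, a pericyte marker (0.70 ± 0.12), each above every FVB IgG array on all 12.

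Here 1116 genes changed, 549 higher and 567 lower, and 56 of them, all lower, differed at least 2-fold. Of 9 atrial markers 7 fell, 8 adjusted over the list alone (adjusted p = 0.209 with an estimated correlation), and of 10 adipocyte markers 6, or 8 adjusted over the list alone (adjusted p = 0.209 with an estimated correlation). B cell markers fell in 2 of 8 cases, also adjusted over the list alone (adjusted p = 0.47 with an estimated correlation). These were the antibody genes Jchain (-1.99 ± 0.59) and Ighm (-1.89 ± 0.54). Of 8 mesothelial markers 1 fell, Krt19 (-0.94 ± 0.30), and 6 adjusted over the list alone (adjusted p = 0.29 with an estimated correlation). Krt18 stood at -0.73 ± 0.25 (adjusted p = 0.053). Fibrillar matrix genes fell in 8 of 34 cases with 1 higher, and in 12 with 1 higher adjusted over the list alone (adjusted p = 0.376 with an estimated correlation). Fmod stood at -1.63 ± 0.40, Mfap4 at -1.57 ± 0.29 and Col14a1 at -0.64 ± 0.16. Fibroblast markers moved with them, 4 of 15 lower and 5 adjusted over the list alone (adjusted p = 0.3275 with an estimated correlation), as did 2 of 22 macrophage markers, also adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). The small leucine-rich proteoglycan Epyc (-2.29 ± 0.48) and Tmem163 (-2.24 ± 0.74) completed the largest falls. In the CCN family 2 of 5 genes fell, 4 adjusted over the list alone (adjusted p = 0.209 with an estimated correlation). They were Ccn4 (-0.88 ± 0.24) and Ccn3 (-0.78 ± 0.23), while Ccn2 was -0.52 ± 0.22 (adjusted p = 0.135). Myh6 was -0.031 ± 0.13 (adjusted p = 0.922) and Prkce 0.22 ± 0.14 (adjusted p = 0.365).

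Heat shock genes rose in 5 of 15 cases, 6 adjusted over the list alone (adjusted p = 0.221 with an estimated correlation), with the chaperones Hsp90aa1 at 0.72 ± 0.11, Hsph1 at 0.67 ± 0.12 and Hspd1 at 0.19 ± 0.052. Pericyte markers rose in 4 of 8 cases, also adjusted over the list alone (adjusted p = 0.209 with an estimated correlation), including the channel subunit Kcnj8 (0.41 ± 0.079). Interferon response genes rose in 4 of 21 cases, 7 adjusted over the list alone (adjusted p = 0.551 with an estimated correlation), with B2m at 0.45 ± 0.12 and Irf1 at 0.35 ± 0.088. The largest rises also held Mycn (0.81 ± 0.21), Aqp7 (0.76 ± 0.21), H2-Ab1 (0.75 ± 0.23), Rhox5 (0.69 ± 0.14), Ano10 (0.69 ± 0.17), Myo10 (0.68 ± 0.11) and connexin 43, Gja1 (0.68 ± 0.16). Other probe sets gave less, with 0.072 and 0.075 for Mycn, 0.33 for Aqp7, 0.36 and 0.13 for Myo10 and at most 0.073 for Gja1. They gave 0.28 and 0.21 for Sin3a, at most 0.28 for Rgs5 and 0.20 and 0.13 for Hsp90aa1.

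The atrial marker level was -4.83 lower in FVB antibody than in FVB IgG arrays (permutation p = 0.00334, adjusted p = 0.02) and moved with the falls in atrial, adipocyte, mesothelial, B cell, CCN family and matrix genes. This level was made after the data were seen from Sln, Myl7 and Myl4, the largest falls here, so its p is no separate support. Without the 10 arrays of high atrial marker level 217 genes changed, 203 of them shared, with 0 atrial, 0 adipocyte, 0 B cell, 0 mesothelial, 0 CCN family and 0 fibrillar matrix genes called, while 2 heat shock, 2 pericyte and 2 interferon genes rose. Sin3a (0.89, adjusted p = 8.73e-05), Rgs5 (0.55, adjusted p = 0.00382) and Hsp90aa1 (0.86, adjusted p = 0.000614) were still called there, and Car3 (-1.61, adjusted p = 0.0639), Adipoq (-1.40, adjusted p = 0.226), Nppa (-0.35, adjusted p = 0.757) and Mfap4 (-1.08, adjusted p = 0.0751) were not. Neither were Ccn4 (-0.31, adjusted p = 0.638) and Ccn3 (-0.33, adjusted p = 0.463), Epyc (-0.83, adjusted p = 0.125) and Ucp1 (-1.06, adjusted p = 0.109). Among the rises Mycn (0.50, adjusted p = 0.261), Aqp7 (0.32, adjusted p = 0.514), H2-Ab1 (0.80, adjusted p = 0.0687), Rhox5 (0.48, adjusted p = 0.178), Ano10 (0.52, adjusted p = 0.273), Gja1 (0.63, adjusted p = 0.111) and Hspd1 (0.14, adjusted p = 0.414) lost the call as well. The arrays left out included FVB IgG replicates 1, 2, 3, 4 and 9, all female, so the smaller group alone may lose a call. H2-Ab1 and Gja1 kept about the size of their rise. With the level as a covariate Ccn4 was -0.43 (adjusted p = 0.504) and Ccn3 -0.28 (adjusted p = 0.725). The FVB IgG mice were numbered 420 to 443 and the FVB antibody mice 338 to 349, so the antibody and the run of numbers cannot be separated here. Without FVB IgG replicate 2, 741 genes changed.

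The difference between these antibody effects was tested as an interaction, the effect in PKCε minus that in FVB mice. The runs of mouse numbers that separate the antibody groups in each line enter this difference too. Sin3a rose in FVB mice but its group mean fell from 0.40 ± 0.22 (SD, n = 10) to -0.24 ± 0.22 (n = 12) in PKCε mice, a difference of -1.38 ± 0.14 (SE, adjusted p = 1.29e-08). Myo10 (-1.23 ± 0.16), the microtubule protein Clasp1 (-1.11 ± 0.13), the cohesin subunit Smc1a (-1.001 ± 0.13), Sntb2 (-1.14 ± 0.17) and Tfrc (-1.38 ± 0.23) had the same sign. The phosphate transporter Slc20a1 (1.76 ± 0.24), the splicing factor Rbm5 (1.68 ± 0.27), the nuclear poly(A) binding protein Pabpn1 (1.64 ± 0.25) and the nuclear RNA Malat1 (1.64 ± 0.28) went the other way. At other probe sets Sin3a was -0.35 on both, Myo10 -0.049 (unadjusted p = 0.761) and -0.17, Clasp1 -0.079, Smc1a -0.13 and 0.083, and Tfrc from -0.32 to 0.11. Slc20a1 was -0.031, Pabpn1 at most 0.28, Malat1 at most 0.34 and Sntb2 up to 0.34, the opposite sign, while those of Rbm5 gave 1.69, 0.15 and 0.10.

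The interaction passed for 479 genes, 259 positive and 220 negative. Positive values also came from Adipoq (2.51 ± 0.66), Car3 (2.45 ± 0.58), Epyc (2.36 ± 0.68), Cyp2e1 (2.35 ± 0.58) and Gdap10 (1.47 ± 0.35), and negative ones from Ereg (-1.46 ± 0.34), Cst6 (-1.10 ± 0.27), Rhox5 (-1.04 ± 0.20) and the apelin receptor Aplnr (-1.02 ± 0.23). Clock genes were called in 5 of 16 cases, all positive, and adjusted over the list alone 8 were positive and 1 negative (adjusted p = 0.344 with an estimated correlation). Hlf stood at 1.37 ± 0.30, Per2 at 1.33 ± 0.35 and Nr1d2 at 0.57 ± 0.14. Other probe sets gave 1.25 for Hlf, 0.23 (unadjusted p = 0.172) for Per2 and 0.19 (unadjusted p = 0.216) for Nr1d2. Adipocyte markers were positive in 2 of 10 cases, 4 adjusted over the list alone, and fatty acid oxidation in 0 of 31, also adjusted over the list alone (adjusted p = 0.642 with an estimated correlation for each). Hadh stood at 0.31 ± 0.096 (adjusted p = 0.059) and Lpl at 0.28 ± 0.093 (adjusted p = 0.0811). The atrial list had 0 of 9 members called, also adjusted over the list alone (adjusted p = 0.642 with an estimated correlation), with Dkk3 at 2.07 ± 0.72 (adjusted p = 0.103) and Nppa at 1.40 ± 0.61 (adjusted p = 0.234). Myh6 was 0.65 ± 0.19 (adjusted p = 0.0423) and 0.048 (unadjusted p = 0.327) at another probe set. It was not called with the atrial marker level (0.69, adjusted p = 0.051) or the Gapdh difference (0.56, adjusted p = 0.0806) as a covariate, or without PKCε IgG replicates 9 and 10 (0.50, adjusted p = 0.145). Ccn2 stood at 0.17 ± 0.31 (adjusted p = 0.859) and Prkce at -0.077 ± 0.20 (adjusted p = 0.91). The interaction passed for 127 genes without the 10 arrays of high atrial marker level, for 725 with the Gapdh difference as a covariate and for 802 with a residual principal component. Without those 10 arrays Adipoq (1.75, adjusted p = 0.297), Car3 (1.74, adjusted p = 0.197), Epyc (0.64, adjusted p = 0.534), Cyp2e1 (1.71, adjusted p = 0.254), Gdap10 (1.40, adjusted p = 0.116) and Myh6 (0.66, adjusted p = 0.138) were not called. Ereg (-1.09), Cst6 (-0.78), Aplnr (-0.58), Hlf (1.28), Per2 (1.35) and Nr1d2 (0.57) lost the call too. Sin3a (-1.53), Clasp1 (-1.21), Slc20a1 (1.81) and Tfrc (-1.17) were still called.

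The comparison of the antibody-treated groups (12 PKCε against 12 FVB mice) asks which effects of the transgene stood under CTGF inhibition, on arrays not used in the comparison under IgG. These groups too came from separate runs of mouse numbers, 38 to 191 in PKCε and 338 to 349 in FVB mice. In PKCε mice the clock score was 1.08 higher (permutation p = 0.0465, adjusted p = 0.124). The Gapdh difference was 0.163 higher (permutation p = 0.0234, adjusted p = 0.0702). Myh7 was 3.05 ± 0.12 higher (8.30-fold, adjusted p = 8.20e-23), Nppa 3.37 ± 0.41, Ltbp2 1.99 ± 0.26 and Col8a1 1.70 ± 0.15, and Cyp2b10 was lower by -4.49 ± 0.36. On all 12 arrays Myh7, Nppa and Col8a1 lay above every FVB antibody array. Mfap4 (2.81 ± 0.28), Fgf6 (2.67 ± 0.22), pleiotrophin Ptn (2.06 ± 0.16), the Wnt modulator Sfrp2 (2.02 ± 0.31), Itgbl1 (2.02 ± 0.19), Dkk3 (1.96 ± 0.49) and the NADPH oxidase Nox4 (1.91 ± 0.23) were also higher.

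Here 5830 genes changed, 2665 higher and 3165 lower. Fetal programme genes were higher in 9 of 10 cases, also adjusted over the list alone and called with an estimated correlation (adjusted p = 0.0432), with Acta1 at 1.73 ± 0.19 and Enah at 0.97 ± 0.099. Of 34 fibrillar matrix genes 30 were higher and 1 lower, also adjusted over the list alone (adjusted p = 0.0871 with an estimated correlation), with biglycan Bgn at 1.38 ± 0.12 and Col5a1 at 0.98 ± 0.086. Fibroblast markers moved with them, 14 of 15 higher and 15 adjusted over the list alone (adjusted p = 0.104 with an estimated correlation). Of 31 genes of fatty acid oxidation 24 were lower, also adjusted over the list alone (adjusted p = 0.25 with an estimated correlation), with Cpt2 at -0.72 ± 0.081 and Etfa at -0.51 ± 0.053. Oxidative phosphorylation had 49 of 66 members lower and 2 higher, 51 and 2 adjusted over the list alone (adjusted p = 0.216 with an estimated correlation), with Uqcrfs1 at -0.42 ± 0.037 and Atp5g1 at -0.31 ± 0.032. Ventricular cardiomyocyte markers moved with the metabolic lists, 8 of 13 lower and 10 adjusted over the list alone (adjusted p = 0.291 with an estimated correlation). All 7 blood and erythroid markers were lower, also adjusted over the list alone (adjusted p = 0.338 with an estimated correlation), with the heme synthesis enzyme Alas2 at -1.30 ± 0.33 and Bpgm at -1.08 ± 0.28. Clock genes were higher in 10 of 16 cases and lower in 1, also adjusted over the list alone (adjusted p = 0.164 with an estimated correlation), with Per3 at 1.36 ± 0.20 and Hlf at 1.03 ± 0.20. Other probe sets gave -0.12 and 0.40 for Per3 and 0.76 for Hlf. Further falls were in Tmprss13 (-2.82 ± 0.20), Aqp4 (-2.14 ± 0.31), Pla2g5 (-1.97 ± 0.21), the prostaglandin synthase Ptgds (-1.67 ± 0.14), Ano10 (-1.65 ± 0.16), Cenpf (-1.63 ± 0.23), Ces1d (-1.62 ± 0.17), the ketone enzyme Bdh1 (-1.59 ± 0.16) and Ttll1 (-1.45 ± 0.16). Ccn2 was 0.91 ± 0.20 higher (adjusted p = 0.00037), above every FVB antibody array on 11 of 12. Myh6 fell by 0.84 ± 0.13 and was -0.12 at another probe set, and Prkce was 0.41 ± 0.13 at the probe set used and -0.37 at another.

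**Figure D3:**
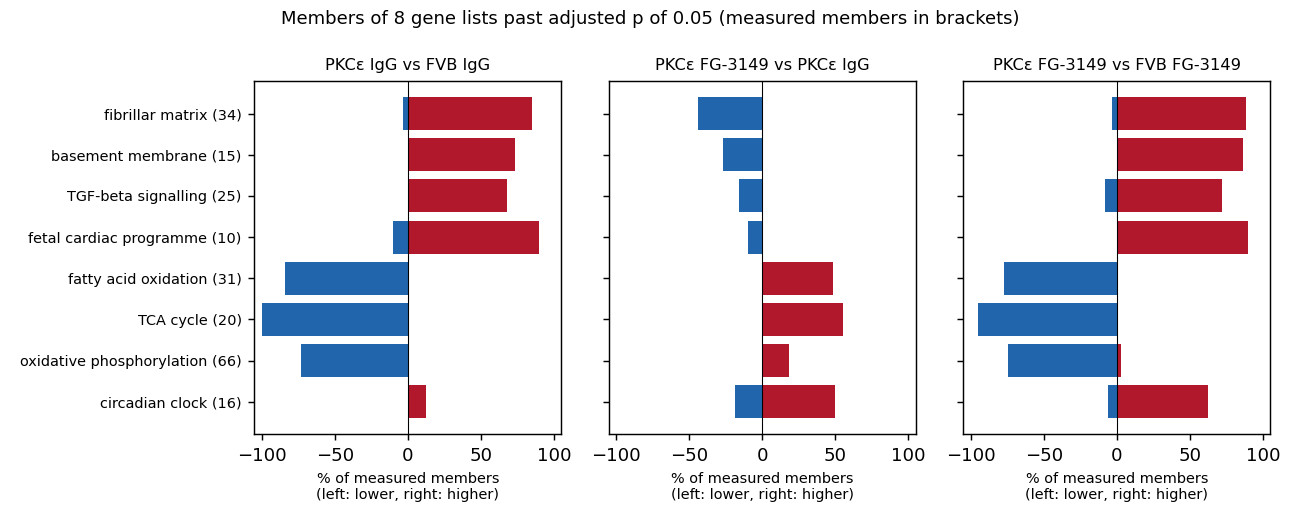
Share of the measured members of 8 gene lists that were higher (right) or lower (left) at an adjusted p under 0.05 over all genes, in percent of the members (horizontal axis), for 3 comparisons; the number of measured members stands in brackets. Of 34 fibrillar matrix genes 29 were higher in PKCε IgG than FVB IgG mice, and 15 were lower in PKCε FG-3149 than PKCε IgG mice.

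Both PKCε comparisons called 1836 genes higher, against 551.8 expected if the calls were independent, and 1625 lower, against 681.6, while 58 went opposite ways. Across genes, which are not independent replicates, their log2 differences had r = 0.765. The antibody effects in FVB and in PKCε mice, which share no arrays, had 64 genes higher in both (27.9 expected), 51 lower in both (21.2 expected) and 47 opposite (49.3 expected), with r = 0.296 across genes.

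Whether PKCε-changed genes moved back under the antibody was measured with divided PKCε IgG arrays. The covariance of the PKCε and antibody effects across genes was -0.0338 ± 0.00379 (SD over 100 divisions), and -0.0399 undivided, against -0.00545 simulated for unchanged groups with shared arrays. The simulated groups held no PKCε effect. Random splits of the PKCε arrays, which kept that effect, gave undivided values as far below 0 as -0.0272. The correlation r was -0.455 divided and -0.589 undivided, the latter against -0.494 in the simulated groups. Of the genes called for PKCε, 77.8% (67.8 to 85.3) had an antibody effect of the opposite sign, 76.2% of those higher and 79.7% of those lower in PKCε mice. The covariance was -0.021 with quantile normalization, -0.025 without PKCε IgG replicates 9 and 10, -0.0525 with the clock score as a covariate and -0.0437 with the Gapdh difference as one. The Gapdh difference followed the same course as the returning genes, 0.332 higher in PKCε IgG than FVB IgG arrays and -0.26 lower under the antibody. The Actb difference was -0.0115 and -0.144 in these comparisons. The mouse numbers of the PKCε groups apply to the covariance too.

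Sex was a term in every comparison of genes between groups, though not in the permutation tests of the array scores, and was tested on its own. Xist and the Y-linked genes led, with Eif2s3y at -5.69 ± 0.25 (female minus male), and Pbdc1, an X-linked gene, was 0.83 ± 0.051 higher in females. In all, 1956 genes differed, 1074 higher and 882 lower in females, and 667 with the clock score as a covariate. With each array centred on its median, 1328 were higher and 606 lower. The PKCε effect under IgG differed between the sexes for 10 genes, all more positive in females, among them Msl3 (1.01 ± 0.14, adjusted p = 0.000219), St14 (1.09 ± 0.17), Crispld1 (2.29 ± 0.36), Chodl (2.92 ± 0.47) and Tnmd (2.07 ± 0.34). Without the 10 arrays of high atrial marker level 343 genes passed this test, and fitted on the compared groups alone 1 did. The run without the 10 arrays lacked FVB IgG replicates 1, 2, 3, 4 and 9, all female, so few FVB IgG females were left. The antibody effect in PKCε mice differed between the sexes for St14 (-1.08 ± 0.16, adjusted p = 0.000395) and Mapk14 (0.90 ± 0.16, adjusted p = 0.00735), neither of which was called in a fit on the compared groups alone. Trim41 (-0.48 ± 0.10, adjusted p = 0.12), Atp6v0a4 (-0.40 ± 0.094) and Tnfrsf11b (-0.94 ± 0.22) did not pass. In PKCε IgG mice the sexes also came from different runs of mouse numbers.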

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

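The tests of atrial tissue and clock phase (their slope tests included), of the runs of mouse numbers and of FVB FG-3149 replicate 11 were chosen only after the result was seen, while the comparisons with random splits were set before. The bounds of the slope tests were written before any slope was fitted. Single arrays were tested for values far from their group in the groups of 10, with 27 found in 374 tests, where chance alone finds about 1 in 20, or 18.7.

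FVB IgG replicate 2 lay apart from its group in 9 measures. Its log2 ratio was -1.27 for Col8a1, -0.984 for Cst6, -2.37 for Irx3, -0.343 for Pln, -1.07 for Kcnj8, -0.279 for Echs1 and -0.454 for Sdhc, and 1.88 for Spon2, and its mean over the pericyte markers was -0.824. FVB IgG replicate 6 had low Adipoq (-2.65) and Car3 (-2.43) and a Mapk14 value of 0.308. FVB IgG replicate 3 had a Nusap1 value of 1.39 and a mean of 0.643 over the interferon response genes.

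In the PKCε IgG group, replicate 9 held the most such values: Jchain at 5.77, Aqp7 at -1.39, Ano10 at -1.56, H2-Ab1 at 0.2765 and a mean of 0.270 over the MHC class II genes. This array also had lung markers, with Sftpc at 9.32 and Sftpa1 at 6.87. Replicate 6 had high Hamp (4.19) and Epyc (2.60), replicate 7 a Ucp1 value of 0.438 and a Rhox5 value of 1.24, and replicate 10 the largest Gapdh 3' minus 5' difference (0.901). Mcm6 was 0.0127 on replicate 4, Mycn 0.8003 on replicate 5 and Hsp90aa1 -0.833 on replicate 1.

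Effects that differed between groups of mice were the next kind. The antibody effect differed between PKCε and FVB mice for 479 genes. It was more positive in PKCε mice for Myh6 (0.647), Adipoq (2.51), Car3 (2.45), Epyc (2.36), Cyp2e1 (2.35), Slc20a1 (1.76), Rbm5 (1.68), Pabpn1 (1.64), Malat1 (1.64), Gdap10 (1.47), Hlf (1.37), Per2 (1.33) and Nr1d2 (0.566). It was more negative for Ereg (-1.46), Sin3a (-1.38), Tfrc (-1.375), Myo10 (-1.23), Sntb2 (-1.14), Clasp1 (-1.11), Cst6 (-1.10), Rhox5 (-1.04), Aplnr (-1.02) and Smc1a (-1.001). The PKCε effect under IgG differed between the sexes for 10 genes, among them Msl3 (1.01), St14 (1.09), Crispld1 (2.29), Chodl (2.92) and Tnmd (2.07). The antibody effect in PKCε mice differed between the sexes for 2 genes, St14 (-1.08) and Mapk14 (0.899).

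Probe sets not assigned to 1 gene were left out of the gene tests, and of these 2246, counted without controls, some passed the same threshold. They numbered 795 between PKCε IgG and FVB IgG, 161 between the FVB groups, 153 between the PKCε groups, 74 for the difference of the antibody effects and 1004 between the antibody-treated groups.

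Random splits of the same arrays, 100 per result with the real one among them, were used to ask whether chance can be excluded. It was excluded, with 1 split as large in each case (the real one), for the PKCε effect under IgG (5235 genes, highest other 1998), the antibody effect in PKCε mice (1093, highest other 250), and the difference of the antibody effects in PKCε and FVB mice (479, highest other 7). The same held for the PKCε effect under the antibody (5830, highest other 1978), sex (1956, highest other 1) and the return under the antibody (covariance -0.0399, nearest other -0.0272). For the overlap of the PKCε effects (3461 genes, highest other 0) the splits removed both PKCε effects at once. A small overlap in the splits then follows, so this count does not test whether the effects are alike. For the antibody effect in FVB mice only the real split reached 1116 genes, which met the bound set before. Another split of the FVB arrays called 1081 genes, nearly as many, so chance is not called excluded for this count. How far such splits overlapped the real groups was not examined, so the source of these calls is not known. For the antibody effect that differs by sex, 4 splits reached the 2 genes seen and none passed it, and for the PKCε effect that differs by sex 7 splits reached 10 genes, the highest 391, so chance was not excluded there. For the numbers of lists chance was not excluded in any comparison: 57 splits reached the 13 lists of the PKCε effect under IgG (highest other 23), 13 the 22 of the antibody in FVB (28), 20 the 15 of the antibody in PKCε (21), 64 the 7 of the difference (26) and 9 the 18 of the PKCε effect under the antibody (21).

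Atrial tissue in some of the samples may account for part of the antibody effect in FVB mice. Slopes on the atrial marker level, fitted in the PKCε arrays alone, gave the right direction for 73.6% of the 1116 called genes, against 61.5% of the genes not called, and the median ratio of predicted to observed change was 0.129. With the atrial marker level as a covariate 23.4% of the genes (261) were still called, above the bound of 5% written after the result was seen. A level from a few genes, entered linearly on the log2 scale, may leave part of an admixture. Atrial tissue as the whole cause was therefore not excluded. The median absolute change went from 0.342 to 0.257 and the median SE from 0.0882 to 0.0980.

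A different clock phase at tissue collection was weighed for the antibody effect in PKCε mice, and the tests did not decide it. Slopes fitted in the FVB arrays gave the right direction for 35.5% of the 1093 called genes, against 49.2% of the genes not called, and the median ratio of predicted to observed change was -0.127. The 35.5% met the bound of 60% or less set for exclusion. It also lay below the genes not called, so the FVB slopes may not hold in PKCε mice and exclude nothing. With the clock score as a covariate 36.8% (402) were still called, above the bound of 5% written after the result was seen. A score from a few genes may hold only part of the phase, so it was not excluded as the whole cause either. The median absolute change of the antibody effect went from 0.318 to 0.325 and the median SE from 0.0843 to 0.109. The run of mouse numbers could account for any share of this effect: 0 runs held at least 3 mice of each group with both sexes, so the data cannot tell.

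FVB FG-3149 replicate 11, labelled female, carried both sexes' genes. Its Xist value lay 1.97 above the highest male array, which excludes a wrong label alone, and 3 of the 3 measured Y-linked genes lay above every other female array, so RNA of a male and a female in the sample may be the cause. Ddx3y, a further gene named in that test, was not measured. Without this array 5201 genes changed between the antibody-treated groups.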

How the results depend on the processing

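The runs with the atrial marker level, the clock score or the Gapdh difference, and those without the 10 arrays of high atrial marker level or the 2 of high lung markers, were chosen only after the result was seen. So was leaving out each array for the lists, while the others were set before. Unless stated otherwise the cause was not tested. Every alternative set before ran, except that no fit without a sex term was possible for the count of genes that differ between the sexes.

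Stricter rules lower counts by construction. At a fold of at least 1.5 there were 1058 genes for the PKCε effect under IgG, 209 for the antibody in FVB, 112 for the antibody in PKCε, 157 for the difference of these, 748 for the PKCε effect under the antibody and 129 for sex. At an adjusted p under 0.01 the antibody gave 458 in FVB and 417 in PKCε mice, the difference 186, the PKCε effect under the antibody 3876, sex 875 and the overlap of the PKCε effects 2296. With genes of the upper part of the SD alone there were 3405 and 3445 genes for the PKCε effects under IgG and antibody, and 21 for the PKCε effect that differs by sex. With every probe set counted, which raises counts by construction, the numbers were 9265, 1889, 1896, 894 and 10216 in the order PKCε under IgG, antibody in FVB, antibody in PKCε, their difference and PKCε under the antibody, then 3368 for sex, 17 for the PKCε effect by sex and 4 for the antibody effect by sex.

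Fewer mice changed some counts strongly. Males alone gave 2169 genes for the PKCε effect under IgG and 57 for the antibody in PKCε. PKCε mice numbered 150 to 196 gave 347 for the antibody, and the sign turned there for Myh6 (-0.11), Ltbp2 (0.040), Dio2 (0.078), Ecrg4 (0.41), Fbln2 (0.086), Col8a1 (0.40), Vcan (0.039), Col5a2 (0.36), Col4a2 (0.13), Acaa2 (-0.071) and Atp5pb (-0.0095). Fitted on the compared groups alone, the PKCε effect by sex gave 1 gene and the antibody effect by sex 0 by limma, against 2 in the full fit, where 991 had an unadjusted p under 0.05.

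Without the 10 arrays of high atrial marker level there were 217 genes for the antibody in FVB, 528 in PKCε, 127 for the difference, 1174 for sex, 343 for the PKCε effect by sex and 5 for the antibody effect by sex. The antibody in FVB then gave 7 lists, the fatty acid oxidation (adjusted p = 0.985) and mesothelial (adjusted p = 0.921) lists turned direction, as did Tmem163 (0.038) and Krt19 (0.0084), and the return was -0.0298. With the atrial marker level as a covariate the antibody in FVB gave 266 genes and 9 lists, the effects by sex 20 (PKCε) and 4 (antibody) genes, and Sln (0.023) and Myl4 (0.098) turned, which follows from their being part of that level. With its linear form there were 275 genes and 6 lists for the antibody in FVB, 1177 genes for sex, 154 and 5 for the effects by sex, Tmem163 at 0.35 and a return of -0.0383.

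With the clock score as a covariate the antibody in PKCε gave 463 genes and sex 667, the difference of antibody effects gave 16 lists, and the return was -0.0525. Per3 (-0.073), Dbp (-0.50), Npas2 (0.021) and Arntl (0.12) turned, which follows from their being part of the score. With the atrial level and the clock score together there were 275 genes for the antibody in FVB, 497 in PKCε, 245 for the difference, 550 for sex, 32 and 4 for the effects by sex, with Sln at 0.0090, Myl4 at 0.12, Per3 at -0.066, Dbp at -0.49, Npas2 at 0.026 and Arntl at 0.13. With the Gapdh difference the antibody in PKCε gave 480, the difference 725, the effects by sex 20 and 4, and the return -0.0437.

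Without the 2 arrays of high lung markers, PKCε IgG replicates 9 and 10, there were 440 genes for the antibody in PKCε and 5 for the antibody effect by sex, the difference of antibody effects gave 11 lists, and the return was -0.0250.

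Quantile normalization gave 726 genes and 9 lists for the antibody in PKCε, 4 and 1 genes for the effects by sex, and a return of -0.0210. A residual principal component gave 802 for the difference and 54 for the PKCε effect by sex, and a floor at the 5th percentile gave 33 for the latter. A replicate block gave 1 for the antibody effect by sex, though replicate numbers do not pair the mice. With the mean of a gene's probe sets the difference gave 12 lists, the return was -0.0260, and Prkce (-0.041) and Trdn (-0.061) turned in the PKCε effect under IgG.

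For lists, an estimated correlation left 1 for the PKCε effect under IgG, 0 for the antibody in FVB, 0 in PKCε, 0 for the difference and 1 for the PKCε effect under the antibody by limma camera, against 13, 22, 15, 7 and 18. The fry test gave 21 for the PKCε effect under IgG, 12 for the antibody in FVB and 1 for the difference.

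Leaving out each array gave 4732 to 5761 genes for the PKCε effect under IgG, 741 (without FVB IgG replicate 2) to 1484 for the antibody in FVB, 751 to 1208 in PKCε, 351 to 521 for the difference and 5201 to 6116 for the PKCε effect under the antibody. It gave 1642 to 2452 for sex, 7 to 17 for the PKCε effect by sex and 2 to 6 for the antibody effect by sex. Lists ranged from 12 to 16, 19 to 23, 12 to 16, 6 to 11 and 17 to 19 in the same order of comparisons.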

Other observations

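Which of these lists to print was chosen only after the result was seen, and no tests were added for them. Ribosomal protein genes were higher in 18 of 33 cases and lower in 1 in PKCε than FVB mice under the antibody, also adjusted over the list alone (adjusted p = 0.25 with an estimated correlation), each by little, with a median of 0.12. Genes of the ER stress response were higher in 10 of 22 cases and lower in 1 in that comparison, also adjusted over the list alone (adjusted p = 0.471 with an estimated correlation). Genes of Wnt and Notch signalling were higher in 10 of 21 cases and lower in 2 there, 10 and 3 adjusted over the list alone (adjusted p = 0.25 with an estimated correlation), and fell in 5 of 21 with 1 higher under the antibody in FVB mice, 7 and 1 adjusted over the list alone (adjusted p = 0.209 with an estimated correlation). Macrophage markers were higher in 7 of 22 cases, but 2 adjusted over the list alone, in PKCε than FVB mice under IgG, and the list was not called (adjusted p = 0.0681, and 0.91 with an estimated correlation).

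Under the antibody in FVB mice, 2 of 9 smooth muscle markers fell, 6 adjusted over the list alone (adjusted p = 0.3 with an estimated correlation), and 2 of 9 complement genes fell, also adjusted over the list alone (adjusted p = 0.376 with an estimated correlation). Genes of the sarcomere held no shift as a list in PKCε IgG mice, with 6 of 22 higher and 5 lower, 8 and 5 adjusted over the list alone (adjusted p = 0.944 with an estimated correlation). T and NK cell markers held 0 of 13 calls by limma in either antibody comparison, where 2780 genes in FVB and 2759 in PKCε mice had an unadjusted p under 0.05.

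The mice of the groups came from separate runs of numbers, with FVB IgG mice at 420 to 443 and FVB antibody mice at 338 to 349. Litter, cage and date of tissue collection were not analysed here.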
